A study of Homo sapiens with 6 samples.

How the data were processed

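The series holds 6 arrays of MCF-7 chromatin, each with 2 colours. Per the labels, immunoprecipitated DNA was labelled with Cy5 and input DNA with Cy3 on every array, and no dyes were swapped. The groups were Pol II in ethanol (2 arrays), Pol II in E2 (2 arrays), Ser5P Pol II in ethanol (1 array) and NELF-A in ethanol (1 array). E2 was read as estradiol, and its dose and time are not given in the sources used here. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

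The deposited scanner files give 1 raw intensity per probe and channel, read with NimbleScan 2.3.78 from a promoter design on hg18, per the file headers. The headers record no background subtraction. The authors' deposited value table gives log2 ratios of the same arrays. Set against the scanner ratios it correlated with r of 0.855 to 0.958 per array, so immunoprecipitated over input is its direction. Its column medians were -0.04, -0.02, -0.04 and -0.02 on the Pol II arrays (vehicle replicates 1 and 2, estradiol replicates 1 and 2), -0.01 for Ser5P and -0.000389 for NELF-A. Its standard deviations were 0.94 to 0.95 on the 4 Pol II arrays, 0.48 for Ser5P and 0.63 for NELF-A, so its Pol II columns look scaled to each other. How it was normalized is not given in the sources used here. Of 386230 tiled probes, 96 are not in it. It served as an alternative.

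From the intensities, log2(Cy5/Cy3) was computed per probe and centred on the median of the tiled probes of its array, with no loess or quantile step, since many promoters carry signal. The 3077 random probes were left out of the fits and served as background. Probes were averaged per region, and 20 of the 18028 regions had fewer than 5 probes and were left out. Regions keep the hg18 coordinates of the files, and 23 lie on unplaced sequence. The only gene table at hand is of another build, so regions were not named and gene lists fixed beforehand were not run.

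The estradiol change was tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the 4 Pol II arrays, with Benjamini-Hochberg adjustment over 18008 regions and an adjusted p threshold of 0.05. The prior had 8.87 degrees of freedom beside 2 residual ones. Occupancy by Pol II needed a group mean of at least 1 and an adjusted p under 0.05 against 0 from the same fit, and for the single arrays a value of at least 1. Named regions followed a rule set before the data were examined. For each direction of change it takes 12 regions, those past the threshold with both estradiol arrays beyond both vehicle arrays by size, filled up by smallest p. It also takes the 10 highest regions per factor and the 8 highest and 8 lowest relative values among Pol II regions. The rule also listed genes, which could not be matched to regions. Groups of neighbouring regions were formed after the data were seen.

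In 20 simulated sets of the 4 Pol II arrays, with 50 changed regions per size among 18008 and one spread for all regions, the fit of estradiol against vehicle recovered on average 0%, 24.8%, 95.6% and 99.9% of log2 changes of 0.5, 1, 1.5 and 2, with 0 false calls. With the session block it recovered 41.9%, 99.9%, 100% and 100%, with 1 to 14 false calls. The simulated noise had the one pooled spread that the blocked fit estimates and assumes. The simulation therefore cannot show how many of that fit's calls on the real arrays are false. The file headers place both replicate 1 Pol II arrays in one scan session and the other 4 arrays in another. Arrays of one session deviated together, with a correlation of 0.539 between the vehicle and estradiol replicate deviations, so session was used as a block. Changes within each session correlated with r = 0.286 across regions.

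Percentiles of sets used 2000 random sets matched in 50 bins of Pol II level, and neighbouring pairs 10000 draws. Alternatives covered loess (span 0.3), mode centring, scaling to one median absolute deviation, spatial centring, normexp (offset 50), the median over probes, the best 5 probes, other probe minimums, dim probes, the deposited values, the session block, a trended robust prior, all 6 arrays in one fit, other thresholds and leaving out each Pol II array.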

Results

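RNA polymerase II (Pol II) was mapped on the promoters of MCF-7 cells, an estrogen receptor-positive human breast cancer line, by chromatin immunoprecipitation and hybridisation to promoter tiling arrays. Cells had received ethanol as vehicle or estradiol (E2), the main natural estrogen. Total Pol II was measured on 2 vehicle arrays and 2 estradiol arrays. Pol II phosphorylated at serine 5 of its C-terminal repeats (Ser5P), the form found near start sites early in transcription, and NELF-A, a subunit of the negative elongation factor that holds Pol II near start sites, were each measured on 1 vehicle array, so their values have no replicate check. The arrays tile 18028 promoter regions of the human genome build hg18 with 386230 probes, at a median of 22 probes per region. Of these regions, 18008 had at least 5 probes and were analysed. The files do not pair the regions with genes, so each is given by its hg18 chromosome, start and end. All values are log2 ratios of immunoprecipitated over input DNA, relative to the median of their array, so a change shared by all regions cannot be seen. The number of arrays limits the precision.

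The arrays differed in brightness and in the spread of their region values. Of the tiled probes, 38.5% and 32.7% were brighter in the immunoprecipitated channel than 95% of the random control probes on the vehicle Pol II arrays of replicates 1 and 2. This share was 50.0% and 40.4% on the estradiol arrays, 28.2% on the Ser5P array and 27.0% on the NELF-A array. In the input channel the share was higher on every array, so it does not measure enrichment. It was 42.1% and 33.0% on the vehicle arrays, 56.9% and 52.3% on the estradiol arrays, 63.3% for Ser5P and 30.3% for NELF-A. The standard deviation of region values was 0.63 and 0.56 in vehicle, 0.78 and 0.52 in estradiol, 0.39 for NELF-A and 0.16 for Ser5P. Across regions the vehicle replicates correlated with Pearson's r = 0.919 and the estradiol replicates with r = 0.937. Vehicle and estradiol arrays of the same replicate number correlated about as closely, with r = 0.954 for replicate 1 and 0.908 for replicate 2. Regions are not independent replicates, and these correlations are descriptive.

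The main comparison asks where estradiol changed the amount of Pol II at promoters. Pol II rose at 4 regions and fell at 1. The 2 largest rises lay close together on chromosome 2, with 1 tiled region between them that was not called. From 11598101 to 11600801 the log2 ratio was -0.36 ± 0.37 (SD, n = 2) in vehicle and 2.08 ± 0.67 in estradiol, a change of 2.44 (SE 0.29), with a limma Benjamini-Hochberg adjusted p = 0.029. From 11589492 to 11592192 it went from -0.77 ± 0.01 to 1.63 ± 0.50 (SD, n = 2), a change of 2.40 (SE 0.23, limma adjusted p = 0.011). On chromosome 12, 52677943 to 52680643, the change was 2.02 (SE 0.27, limma adjusted p = 0.045). On chromosome 21, 42659213 to 42661913, it was 1.80 (SE 0.22, limma adjusted p = 0.029). The region that fell lay on chromosome 2, 143349464 to 143352164, and went from 1.26 ± 0.08 to -0.32 ± 0.00342 (SD, n = 2), a fall of -1.59 (SE 0.18, limma adjusted p = 0.026). With the median over probes in place of the mean, the 4 rises were 1.62 to 2.55 and the fall -1.66, but limma called 0 regions (adjusted p of 0.115 to 0.309 at these 5, with 365 rises and 202 falls at an unadjusted p under 0.05). Leaving out 1 array gave 15 rises without vehicle replicate 2, 31 without vehicle replicate 1, 33 without estradiol replicate 1 and 549 without estradiol replicate 2, and 5, 2, 55 and 40 falls.

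At the 4 regions that rose, many more probes were brighter than most random probes with estradiol. Between 17.4% and 42.0% of their probes were brighter than 95% of the random probes in vehicle, against 91.3% to 100% in estradiol. Over all tiled probes the share was 38.5% and 32.7% on the vehicle arrays and 50.0% and 40.4% on the estradiol arrays. The regions were chosen for a change on these same arrays, so their shares are not separate support. At the region that fell, the share went from 58.3% to 27.1%. The other 8 regions named for the smallest p among increases had changes of 1.21 to 1.80 and limma adjusted p of 0.053 to 0.090, and none passed. They included 3 more regions of the same stretch of chromosome 12 and the region of chromosome 2 from 11595330 to 11598030, with a change of 1.76 (SE 0.27). They also included chromosome 19, 43516097 to 43518797, which already carried Pol II in vehicle (0.89 ± 0.04, SD, n = 2) and reached 2.42 ± 0.39. The other 11 regions named among decreases had changes of -1.46 to -0.93 and limma adjusted p of 0.072 to 0.262. At 10 of these 11 the vehicle mean was at least 0.56, and the highest was 2.15 ± 0.12 (SD, n = 2) on chromosome 6, 152168178 to 152170878.

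**Figure D1:**
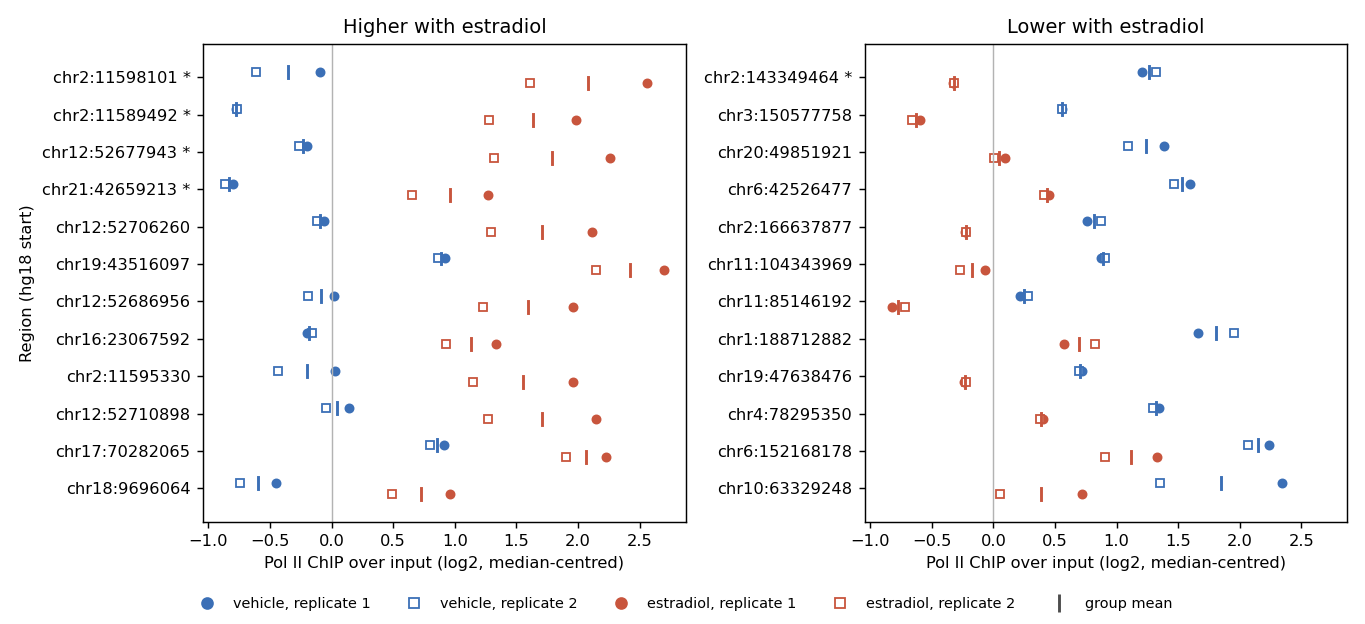
Pol II log2 ratio (horizontal axis, immunoprecipitated over input, centred on each array's median) on each of the 4 arrays at the 12 regions named for increases (left) and the 12 named for decreases (right), with filled circles for replicate 1, open squares for replicate 2 and vertical bars for group means. An asterisk marks the 4 increases and the 1 decrease that passed, and at every region named both estradiol arrays lie beyond both vehicle arrays.

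The 2 replicate numbers were also 2 scan sessions, each with 1 vehicle and 1 estradiol Pol II array. With session as a block in limma, Pol II rose at 300 regions and fell at 117, and all 5 regions called without the block were among them. Within session 1 the median change was 0.88 over the 300 risers and -0.56 over the 117 fallers, and within session 2 it was 0.51 and -0.74. The risers' medians in sessions 1 and 2 depended on the scaling. They were 0.60 and 0.52 after scaling to one median absolute deviation and 0.55 and 0.56 with the deposited values. Each session holds 1 array per treatment and gives no test of its own. The blocked fit had 1 residual degree of freedom, and limma then gave all regions one pooled standard error of 0.15, so its calls rest on that shared spread. The same 4 arrays parted by session in place of treatment gave 58 called regions, against 5 by treatment.

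The balance of rises and falls depended on the scaling. In the blocked fit 71.9% of calls were rises, but after loess within each array there were 269 rises and 365 falls (42.4%), and with the authors' deposited values 217 and 234 (48.1%). Without the block, loess gave 22 and 17, the deposited values 29 and 23 and mode centring 9 and 1. All 300 risers kept a change above 0 and all 117 fallers a change below 0 under loess, deposited values, mode centring and scaling to one median absolute deviation. The smallest changes by which they were chosen on these same arrays were 0.50 and -0.50, so keeping the sign is not separate support. Of the 300 risers, 224 were called again in the blocked fit after loess and 202 with the deposited values, and of the 117 fallers, 116 and 112. Mode centring in the blocked fit gave 288 rises and 45 falls (86.5%), and all 45 were among the 117.

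The regions that rose in the blocked fit often lay next to each other. Of the 300, 74 lay in 30 groups in which each member was at most 50000 bp from the next. Of the 117 fallers, 8 lay in 4 groups. A larger set holds more neighbours by chance, and random draws were made for the risers only. These shares therefore do not show that neighbouring is particular to rises. The largest group covered chromosome 12 from 52663020 to 52734427, where all 7 tiled regions rose, by 0.73 to 2.02. Of these, 6 had vehicle values between -0.24 and 0.42, and in estradiol all 7 reached 1.46 to 1.82. A neighbouring region upstream in coordinates, 52650995 to 52653695, had 1.61 ± 0.02 (SD, n = 2) in vehicle, a change of 0.21 (SE 0.26) and was called in neither fit. On chromosome 9, 129729091 to 129784516, all 4 tiled regions rose by 0.54 to 0.96. On chromosome 2, 11589492 to 11600801, and on chromosome 21, 42659213 to 42691469, all 3 tiled regions rose, by 1.76 to 2.44 and by 0.55 to 1.80. Chromosome 17 held 3 further groups of 3, of which the one from 36914891 to 36940360 had a mean of 0.74 in vehicle and 1.53 in estradiol. After loess or with the deposited values, 6 of the 7 regions on chromosome 12 were called.

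**Figure D2:**
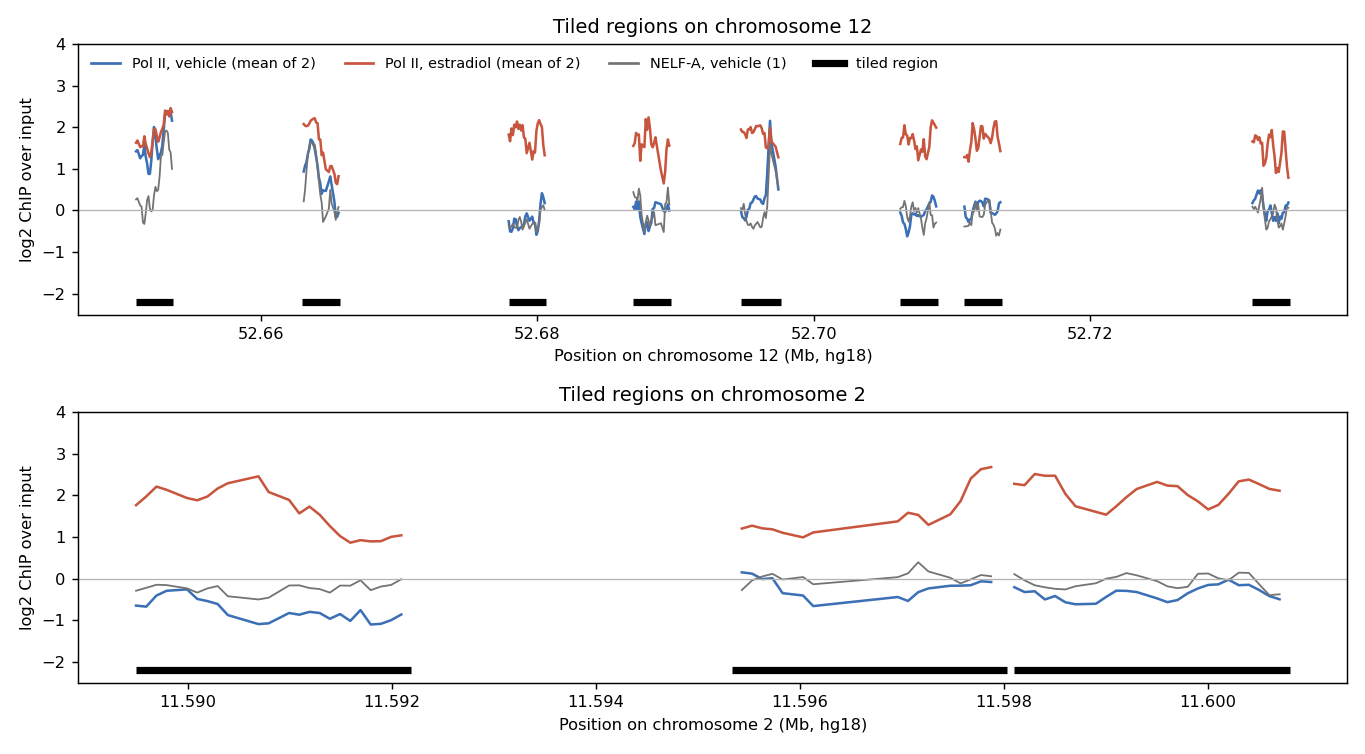
Log2 ratio over input (vertical axis, running mean of 3 probes) against hg18 position in Mb for the tiled regions (black bars) of chromosome 12 around the group of 7 risers and of chromosome 2 around the group of 3, with Pol II as the mean of 2 arrays per treatment and NELF-A from 1 vehicle array. Estradiol Pol II lies above vehicle Pol II along most of each riser, and the region at 52650995 shows both at a similar level.

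Fallers started from higher Pol II levels than risers. The median vehicle value was -0.02 over all regions, 0.09 (quartiles -0.21 and 0.38) over the 300 risers and 0.69 (quartiles 0.25 and 1.11) over the 117 fallers. With estradiol the medians were 0.85 and -0.01. Only 11 of the 300 risers were occupied by Pol II in vehicle and 109 in estradiol, by the threshold described next. Of the 117 fallers, 32 were occupied in vehicle and 7 in estradiol. Part of such a difference in starting level comes from choosing regions by a change that uses the same vehicle arrays.

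The vehicle arrays also ask which promoters carried Pol II. A region was called occupied at a mean log2 ratio of at least 1 with a limma adjusted p under 0.05 against the array median. In vehicle the p criterion removed no region, so the call there is the cutoff alone. Pol II occupied 1328 regions in vehicle (7.37%) and 1989 in estradiol, with 1221 in both. The higher count in estradiol came from replicate 1. By single arrays, 1723 and 1097 regions reached 1 in vehicle and 3201 and 900 in estradiol. After loess the order turned, with 575 regions in vehicle and 495 in estradiol, and the deposited values gave 801 and 779. Low values were also common, since 246 and 181 regions lay as far below the array median in vehicle.

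The highest Pol II value in vehicle was 2.60 ± 0.08 (SD, n = 2) on chromosome 1, 148088604 to 148091340, which also had the highest NELF-A value (2.27) and the second highest Ser5P value (0.82). Chromosome 8, 102571961 to 102574661, followed at 2.36 ± 0.12 (SD, n = 2), with 1.61 for NELF-A and 0.24 for Ser5P. Another region of chromosome 1, 148078853 to 148083142, had 2.32 ± 0.02. Chromosome 11, 62363704 to 62366404, had 2.31 ± 0.05 for Pol II, 1.94 for NELF-A and 1.01 for Ser5P, and was the 1 region at which Ser5P reached 1. At the 10 regions with the highest vehicle Pol II, the change with estradiol lay between -0.47 and 0.37, and none was called in either fit.

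NELF-A reached 1 at 763 regions (4.24%), and these were largely regions with Pol II. Of the 763, 611 (80.1%) were occupied by Pol II in vehicle, against 56.3 if the lists were independent. Of the 1328 Pol II regions, 46.0% carried NELF-A. These shares depend on the scaling, since the arrays differ in spread. After scaling to one median absolute deviation, 710 regions carried Pol II, 1593 NELF-A and 575 both, which is 36.1% of the NELF-A regions and 81.0% of the Pol II regions, against 62.8 for independent lists. NELF-A was higher where Pol II was higher. Its median was -0.10 at regions with vehicle Pol II below 0, 0.15 from 0 to 0.5, 0.53 from 0.5 to 1, 0.90 from 1 to 1.5, 1.34 from 1.5 to 2 and 1.64 at the 26 regions above 2. Across the 18008 regions Pearson's r was 0.835 and Spearman's rho 0.814. The NELF-A array shared its scan session with Pol II replicate 2, for which r was 0.811. After loess the overlap was 253 of 575 Pol II and 368 NELF-A regions, and with the deposited values it was 281 of 801 and 359.

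Ser5P followed total Pol II weakly. Its median was 0.03 at regions with vehicle Pol II below 0, 0.12 from 1 to 1.5 and 0.39 above 2. Pearson's r with vehicle Pol II was 0.271 and Spearman's rho 0.254, and with replicate 2 of the same session r was 0.248. Among the 1000 highest regions of each factor, a list size chosen after the data were seen, Pol II and Ser5P shared 145 regions, Pol II and NELF-A 620 and the vehicle Pol II replicates 745, against 55.5 for independent lists. Of the 10 regions with the highest Ser5P, 6 had vehicle Pol II above 1 and 4 lay between -0.08 and 0.10. One of these 4 was chromosome 19, 16997969 to 17000669, with 0.72 for Ser5P, -0.06 ± 0.19 (SD, n = 2) for Pol II and 0.12 for NELF-A.

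**Figure D3:**
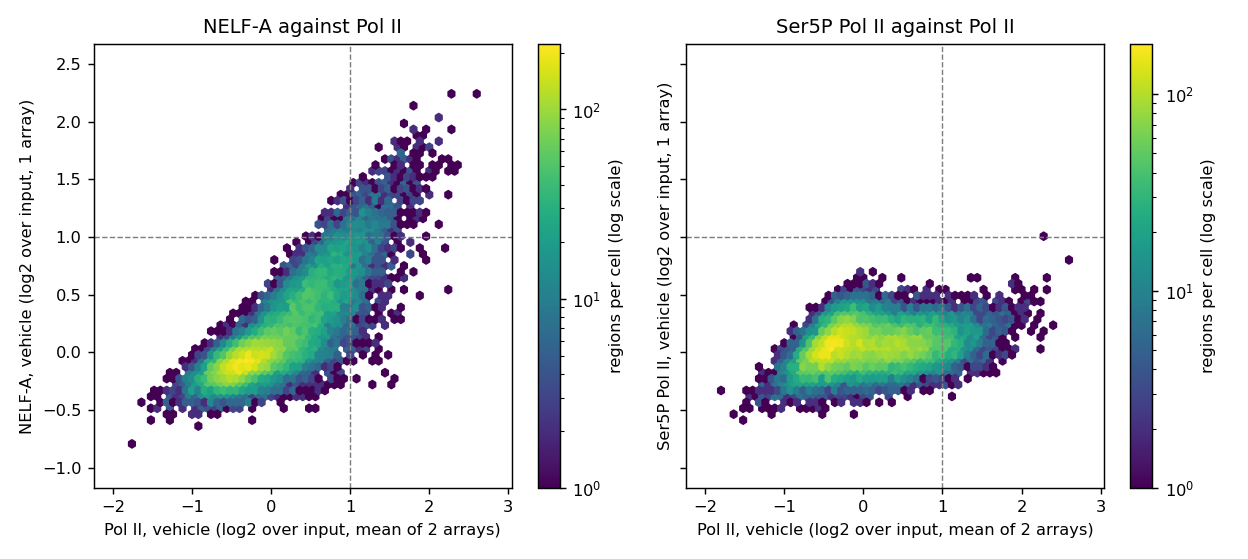
NELF-A (left) and Ser5P Pol II (right) log2 ratio over input on 1 vehicle array each against the mean vehicle Pol II log2 ratio of 2 arrays, for 18008 regions, with colour for the number of regions on a log scale and dashed lines at 1. NELF-A climbs with Pol II (r = 0.835), while Ser5P stays in a narrow band (r = 0.271).

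Some regions occupied by Pol II had far less NELF-A or Ser5P relative to Pol II than others, with each factor scaled to the same standard deviation over regions. Regions were ranked by the difference of the scaled values and were not matched on Pol II level. The extremes of NELF-A and Ser5P rest on 1 array each, so noise of that array can place a region among them. The 8 regions lowest in NELF-A relative to Pol II had NELF-A between -0.27 and 0.57 at vehicle Pol II of up to 2.22. On chromosome 5, 132233712 to 132236412, Pol II was 1.52 ± 0.17 (SD, n = 2) and NELF-A -0.27. On chromosome 1, 76033017 to 76035717, Pol II was 1.57 ± 0.18 and NELF-A -0.22. The 8 highest had NELF-A of 1.44 to 2.13 at Pol II of 1.04 to 1.84, led by chromosome X, 101738613 to 101741313, with 2.13 for NELF-A and 1.84 ± 0.19 for Pol II. For Ser5P, the 8 highest lay between 0.46 and 1.01 and the 8 lowest between -0.39 and 0.01. Chromosome 1, 28702954 to 28705654, had Ser5P of 0.68 at Pol II of 1.36 ± 0.09, and chromosome 1, 155001697 to 155004397, -0.39 at 1.16 ± 0.06. Without the scaling, the lists of 8 shared 3 and 7 regions with these for NELF-A and 4 and 1 for Ser5P, high and low.

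Along the occupied regions, NELF-A was highest near the place where Pol II was. The start site of each region is not given in the files, so 873 occupied regions of 2700 bp were turned to put the end with more Pol II on the estradiol arrays first. Mean vehicle Pol II peaked 700 bp from that end at 2.04 and 1.84 on replicates 1 and 2, and NELF-A peaked in the same bin at 1.65. From 2000 bp on, Pol II was 0.53 and 0.47 in vehicle and 0.61 and 0.27 in estradiol, NELF-A -0.00229 and Ser5P -0.04. The regions were chosen for a high vehicle Pol II mean and turned by estradiol Pol II, which shapes the far end on those arrays, so how fast each factor falls off cannot be compared. Mean Ser5P peaked at 400 bp, at 0.39, as did estradiol Pol II replicate 2, at 1.72. The best window of 5 probes per region lay at a median of 600 bp for Ser5P and 634 to 650 bp on the Pol II arrays. Within regions the median difference of Ser5P from vehicle Pol II was 0, but the median absolute difference was 200 bp. The mean difference was 52.7 bp (SE 18.8) from replicate 1 and 38.6 bp (SE 19.0) from replicate 2, farther from the Pol II-richer end. Estradiol Pol II differed from vehicle Pol II of the same replicate by -34.7 bp (SE 9.94) and -50.0 bp (SE 11.1). These SEs are over regions and not over arrays. The profile peak and the mean difference of Ser5P point in opposite directions, so no shift of Ser5P can be read from them. The best window lay within 200 bp of that of vehicle Pol II replicate 1 at 81.1% of regions for NELF-A, 83.2% for Pol II replicate 2 and 51.3% for Ser5P.

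**Figure D4:**
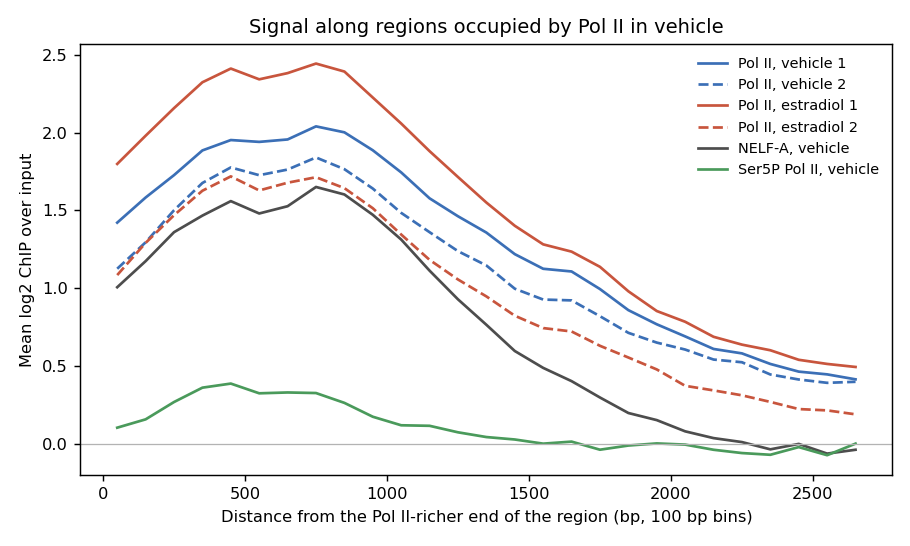
Mean log2 ratio over input in bins of 100 bp against distance in bp from the Pol II-richer end, over 873 regions of 2700 bp occupied by Pol II in vehicle, with 1 line per array. NELF-A and vehicle Pol II peak in the same bin, and Ser5P stays low along the region.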

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

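Of the alternatives, those that pair normalization with the replicate block and the lists of 1000 regions were chosen after seeing the data. None of the 24 regions named for the estradiol change turned direction under the alternatives run for that change. These regions were chosen on the same arrays, so this is not separate support. Of the 5 called regions, 4 passed under 21 of 22 alternatives and the region of chromosome 12 under 20, with limma adjusted p up to 0.309. The other 19 of the 24 passed with the replicate block. The causes of the shifts below were not tested unless stated. The gene lists and their alternatives were not run, since regions could not be named.

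For the estradiol change, 4 regions rose and 1 fell. The counts of rises and falls were 22 and 17 after loess, 74 and 26 after scaling to one median absolute deviation, 43 and 11 after normexp, 29 and 23 with deposited values, 17 and 8 with the best 5 probes, 109 and 31 with a trended robust prior and 13 and 4 at an adjusted p of 0.10. They were 359 and 158 at an unadjusted p under 0.05, and 27 and 7 when only regions occupied in either treatment were tested. That choice adjusts over fewer regions. It also uses the same group means that are compared, so it is not independent of the change. Mode centring gave 9 rises and moved the median change of all regions from 0.05 to 0.12. The median over probes gave 0 and 0 in limma, with 365 and 202 at an unadjusted p under 0.05. With the replicate block there were 300 and 117. The replicate block gave 269 and 365 after loess, 289 and 116 after scaling, 288 and 45 after mode centring and 217 and 234 with deposited values. Leaving out 1 array gave 15 to 549 rises and 2 to 55 falls, with the lone array assumed to vary like the other group. Without estradiol replicate 2 there were 549 rises, without estradiol replicate 1 33 rises and 55 falls, without vehicle replicate 1 31 and 2, and without vehicle replicate 2 15 and 5.

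For occupancy, the values are regions with vehicle Pol II (1328), estradiol Pol II (1989), Ser5P (1) and NELF-A (763), in that order. Loess gave 575, 495, 0 and 368, scaling 710, 1073, 10 and 1593, deposited values 801, 779, 0 and 359, and the best 5 probes 6503, 7242, 83 and 4881. A threshold of 0.58 gave 3719, 4558, 22 and 2664, and one of 1.5 gave 237, 434, 0 and 101. A threshold per array, at which values as far below the median number at most 5% of those above, was 1.23 and 1.52 on vehicle and 1.08 and 1.27 on estradiol Pol II arrays, 0.55 for Ser5P and 0.38 for NELF-A. For Pol II both arrays of the group had to reach it, in place of their mean, and it gave 161, 312, 34 and 4288. Mode centring gave 1355 for NELF-A, normexp 4 for Ser5P and leaving out dim probes 2. Without estradiol replicate 1 estradiol Pol II occupied 900 regions and without replicate 2 3201.

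The overlap of vehicle Pol II with NELF-A (611) was 253 after loess, 281 with deposited values, 920 after mode centring, 4757 with the best 5 probes, 2233 at 0.58, 87 at 1.5 and 157 at the threshold per array, and 575 after scaling, from lists of other sizes. That with Ser5P (1) was 0 after loess, normexp, with deposited values and at 1.5, 6 after scaling, 55 with the best 5 probes, 9 at 0.58, 8 at the threshold per array and 145 in lists of 1000. Of the 8 highest and 8 lowest regions relative to Pol II, unscaled ratios kept 4 and 1 for Ser5P and 3 of the highest for NELF-A. On the NELF-A and Ser5P arrays, 27.0% and 28.2% of probes were above 95% of the random probes in the immunoprecipitated channel. In the input channel 30.3% and 63.3% were, and each factor has 1 array.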

Other observations

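The comparisons of signal shape, the matched sets and the tests of array noise, of the fallers' session ratio and of chance placement were chosen only after the result was seen. Pol II at the risers was less peaked along the region than at other regions of the same estradiol level. Over 263 risers of 2700 bp, the best 5 consecutive probes on the estradiol arrays lay 0.59 (median, quartiles 0.38 and 0.79) above the region mean. Sets of other regions with the same estradiol Pol II had a median of 0.93 (95% of sets 0.85 to 0.98), and 0 of 2000 sets were as even. The 63 risers in groups of neighbours had 0.43 against 0.90, and the 200 outside groups 0.62 against 0.92. The 104 fallers went the other way, with 0.71 against 0.51. Risers were chosen by the mean over all probes of a region, which favours broad rises, and the other regions were not matched on vehicle Pol II, so the comparison describes these sets only.

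NELF-A and Ser5P were measured in vehicle only. The 300 risers had a median NELF-A of 0.06, as did regions of the same vehicle Pol II (0.06), but regions matched on all 4 Pol II arrays had 0.29. The 117 fallers had 0.36, below the 0.46 of regions matched on vehicle Pol II and above the 0.17 of regions matched on all 4 Pol II arrays, so both comparisons depend on the matching. Ser5P was below that of matched regions in both sets, by little at the risers. The fallers had a median of -0.05, below 0.09 and 0.07 in the sets matched on vehicle and on all 4 arrays and lower than all 2000 sets of each kind. The risers had 0.04, below 0.07 and 0.08, with 1.2% and 0.15% of the matched sets lower. The median over all regions was 0.05, so the risers lay near the typical level of the array. Neighbouring regions are not independent, so these shares are descriptive.

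The share of regions occupied by Pol II in vehicle lay between 4.04% of 717 regions on chromosome 9 and 10.6% of 952 on chromosome 6, among chromosomes 1 to 22 and X. The differences between chromosomes were not tested. The shares of risers were highest on chromosomes 17 (30 of 1012, 2.96%) and 21 (7 of 239, 2.93%), against 300 of 18008 over all regions. Chromosomes 8 (2.69%) and 9 (2.51%) were close. Of the 7 risers on chromosome 21, 3 lay in 1 group of neighbours. The densest stretches were chromosome 11, 62070408 to 62894336, with 12 of 29 regions occupied, and chromosome 1, 148018711 to 148962176, with 11 of 29 occupied by Pol II and 11 by NELF-A. On chromosome 6, 33016295 to 33881971, 8 of 26 were occupied by Pol II and 1 by NELF-A.

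Rises with estradiol were larger in session 1 than in session 2, with a median ratio of 1.73 (bootstrap interval 1.61 to 1.80) over the 300 risers. This interval and those below resample regions, which are not independent. With 1 array per treatment in each session, they do not measure the spread between arrays or sessions. A stronger response at all regions in session 1 would also enlarge the falls, but the ratio over the 117 fallers was 0.837 (0.735 to 0.919). The fallers' ratio was not computed after scaling or loess, and the estradiol arrays differ in range. It therefore cannot decide on such a response. After scaling every array to one median absolute deviation the risers' ratio was 1.14 (1.09 to 1.20), and after loess it was 1.15 (1.07 to 1.21). With the deposited values it was 0.923 (0.869 to 0.994), so the direction turned. The wider ratio range of the estradiol array of session 1 and an intensity-dependent dye bias are therefore both candidate explanations, and they stay open together, since either correction reduces the difference, and a difference in treatment between sessions was not tested.

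Ser5P followed Pol II weakly across regions, with r = 0.271. Noise that differs between the probes of a region is argued against as the whole cause. Divided by the root of both split-half reliabilities (0.632 for Ser5P and 0.971 for Pol II), r was 0.345, while NELF-A reached 0.871. Noise shared by all probes of a region on the Ser5P array counts as signal in these reliabilities. With 1 Ser5P array the test cannot decide on such shared noise, which stays open. Dye bias that depends on intensity is argued against as the cause, since r after loess was 0.296. Dye bias particular to single probes was not tested, as no dyes were swapped. The yield of the Ser5P antibody stays open, as there is 1 array, and no biological explanation was tested.

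Risers lay next to each other in 44 neighbouring pairs. Random placement gave at most 11 pairs in 10000 draws, and draws matched on the density of tiled regions at most 10 (permutation test, one-sided, p = 1e-04 for each, the smallest these draws can give). This argues against both independent chance placement and uneven tiling. The draws treat regions as independent, so they cannot tell a shared change from array error shared by neighbouring regions. No draws were made for the fallers or for the split by session. A change of input DNA is argued against too. Over the 74 regions in groups the input fell by a median of -14.8% of the rise, a small increase (bootstrap interval over regions -19.7 to -8.77). As a hypothesis, the groups are consistent with Pol II entering whole transcription units after estradiol, which needs gene annotation of hg18 and was not tested.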
